A study of Mus musculus with 12 samples.

How the data were processed

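Single-cell RNA sequencing was done on cells dissociated from whole spinal cords of mice at 120 days of age, with the 10x Genomics 3′ v3.1 chemistry, which counts each captured mRNA molecule once by its unique molecular identifier (UMI). The 12 libraries fell into 3 groups of 4 by their sample titles: wild-type mice (WT; libraries N4, N8, N9 and N10), SOD1-G93A mice given vehicle (A2, A5, A7 and A11) and SOD1-G93A mice given a RIPK1 inhibitor (B3, B4, B8 and B12). SOD1-G93A mice carry a mutant human SOD1 transgene and develop a motor neuron disease used as a model of amyotrophic lateral sclerosis. The inhibitor, GSK'547, blocks the kinase activity of RIPK1, a kinase of cell death and inflammatory signalling, and was given to female mice from day 70, per the series design text. The tissue label names SOD1-G93A cord for every library, WT included, so groups were taken from the titles. Per the labels' protocols, cords were perfused and digested with papain in the presence of transcription and translation inhibitors, and myelin was removed by centrifugation. The labels do not state whether WT mice received vehicle or gavage, nor that each library code is a separate animal, so p-values measure the spread between these libraries.

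The deposited files hold UMI counts per gene and barcode, not normalized. The submitters' processing notes name Cell Ranger 6.0.0 and the mm10 genome build. Counts of 32285 genes were deposited for 15854 barcodes, with no barcode under 500 UMIs. The human SOD1 transgene has no feature of its own in the files. Gene coordinates were taken from the GENCODE M21 annotation of GRCm38 (mm10) by gene identifier, and 32158 of the 32285 identifiers matched. The total was 142210259 UMIs, from 1809266 to 24116541 per library.

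From these counts, barcodes with at least 400 genes, at least 800 UMIs and at most 15% mitochondrial UMIs were kept, and doublets were marked per library with Scrublet as implemented in scanpy 1.11.5, at an expected rate of 0.8% per 1000 barcodes. The filter removed 3133 barcodes, 29.1% ± 3.63 (SD, n = 4) per WT library, 18.0% ± 7.78 (n = 4) with vehicle and 21.5% ± 12.3 (n = 4) with inhibitor. Scrublet marked 108 doublets (0.85%), and 12613 cells remained. Counts were scaled per cell and log-transformed, and 2000 variable genes, 30 principal components and 15 neighbours gave 26 Leiden clusters at resolution 1.0 (leidenalg 0.10.2, anndata 0.12.19, Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3). Clusters were named from marker genes fixed before the data were examined. The thresholds for naming were set after the data were seen: a mean excess in marker detection of at least 0.4 over the other clusters, at least 3 markers detected in at least 25% of the cells, and no other class scoring above 0.5 of the best. A cluster also stayed unnamed where other classes led its top 10 genes, or where its median UMI count was under 33.3% of its libraries' own with no marker of that class among the top 10. These thresholds left 4 clusters unnamed, holding 5.84% ± 1.36 (SD, n = 4) of WT cells, 9.28% ± 0.416 (n = 4) of vehicle cells and 8.26% ± 2.11 (n = 4) of inhibitor cells. The largest, cluster 9, was led by Cst7, Tyrobp and ribosomal genes at a median of 1541 UMIs and held 1.25% ± 0.59, 5.00% ± 1.35 and 4.46% ± 1.06 of cells in the same order. Cluster 15 carried endothelial and pericyte markers together, at 3.16% ± 0.96, 1.93% ± 1.09 and 1.56% ± 1.13. Cluster 16 was led by H2-Aa and Cd74, at 0.52% ± 0.43, 1.82% ± 0.98 and 1.59% ± 0.75, and cluster 23 by Hopx and Npb, at 0.90% ± 0.72, 0.53% ± 0.22 and 0.65% ± 0.39.

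Raw counts were summed per library and class, and a class was tested where at least 3 libraries of each group held at least 20 of its cells. Microglia-like and oligodendrocyte-like cells met this with 4 libraries per group, and astrocyte-like cells with 3 WT, 3 vehicle and 4 inhibitor libraries. Endothelial, ependymal and oligodendrocyte precursor classes did not meet it and were compared by share of cells only. The tests used edgeR 4.0.16 in R 4.3.3 (filterByExpr, TMM scaling, quasi-likelihood F-test) in 1 fit per class over all 3 groups, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. CPM below is the summed count scaled to a library total of 1000000, as mean ± SD over libraries, and SE is the standard error of the log2 fold change. Log2 fold changes of genes with few counts depend on the prior count, so a gene with no UMI in one group is given as a lower bound against 3 UMIs over that group, and a gene with 1 to 3 UMIs as a ratio with its 95% counting interval. Gene lists fixed before the data were examined (263 of 265 listed members matched a symbol in the files) were tested with camera in limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists and both main comparisons within a class, and again with an estimated correlation and with fry (statmod 1.5.0). Clec7a was not analysed here. Shares of cells were compared by two-sided exact permutation tests over the 70 assignments of 8 libraries, adjusted over both comparisons and all named classes; the smallest p these can give is 0.0286.

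The genes named below follow a rule fixed before the data were examined. It takes the 8 largest rises and 8 largest falls in microglia (4 of each in the other classes) among genes with an adjusted p under 0.05, a mean log2 CPM of at least 4 and no overlap between the groups' libraries, leaving out predicted and Rik genes, or the 5 smallest p-values where none passes. It adds the 2 members of each list with the smallest p (in other classes, of lists past the threshold), Sod1 and Ripk1. Genes named outside the rule are said to be so. Some genes the rule names are not reported here. Reads of near-identical genes (C4b and C4a, the Serpina3 family, histocompatibility genes, the Ms4a family) can be split or lost between copies in counting, so those values are less certain. Library numbers 1 to 6 and 7 to 12 hold 2 libraries of each group and served as a further term in an alternative fit; the labels do not call them batches. After the data were examined 2 lists were added, of glucocorticoid-responsive genes and of clock genes, both written after the genes that changed in oligodendrocytes had been seen and used only as hypotheses.

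The count test was checked on simulated data drawn from the real means and library sizes with known changes. In microglia it recovered 80.6% of genes changed 2-fold and 50.7% of those changed 1.5-fold between inhibitor and vehicle (73.1% and 26.9% between vehicle and WT), in oligodendrocytes 76.1% and 34.3% (64.2% and 37.3%), and in astrocytes 26.9% and 1.5% (41.8% and 7.5%). Alternatives were DESeq2 1.42.0, limma-voom, relative log expression size factors, no filter on low genes, a floor of 10 CPM in at least 4 libraries, looser and stricter cell filters, doublets kept, other clustering resolutions, cells named one by one, fits of the compared groups only, and leaving out each library in turn. A term for library numbers and thinning every library to 771015 UMIs, the summed count of the shallowest microglial library, were also planned. Leaving out both WT libraries under 500 cells, estimated correlations and fry for the other classes, fits within each set of library numbers, the share of microglial RNA without each library, and the relation between comparisons without each library or in oligodendrocytes were added after the data were seen. Replicate codes are not shared between groups, so no pairing was used. All 18 pairs of libraries within groups differed by more than sampling noise (chi-square per degree of freedom 9.02 to 43.2). Figures were drawn with matplotlib 3.10.9.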

Results

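The series measured gene expression in single cells of spinal cord from mice at 120 days of age, in 3 groups of 4 libraries: WT mice, SOD1-G93A mice given vehicle, and SOD1-G93A mice given the RIPK1 kinase inhibitor GSK'547 from day 70. Treatment began before motor deficits were noticeable, per the design text, and the comparisons ask what the disease changed in each cell class and whether the inhibitor altered it. Libraries held 254 to 2326 barcodes and 1809266 to 24116541 UMIs. After filtering, 12613 cells remained, 810.2 ± 615 (SD, n = 4) per WT library, 1111 ± 582 (n = 4) per vehicle library and 1232 ± 781 (n = 4) per inhibitor library. The median UMI count of kept cells was 8140.4 ± 397 in WT, 10335 ± 1793 with vehicle and 10475 ± 3065 with inhibitor (SD, n = 4 each). Vehicle library A11 (7682) and inhibitor library B8 (7435) lay below every WT library.

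Cells fell mainly into glial classes. Microglia-like cells (6067) expressed Tmem119, P2ry12 and C1qa, oligodendrocyte-like cells (2797) Mog, Mag and Opalin, and astrocyte-like cells (1124) Aqp4 and Slc7a10. Smaller classes were endothelial-like (561), ependymal-like (398), oligodendrocyte precursor-like (297), pericyte-like (155), T or NK cell-like (117), border macrophage-like (70), neuron-like (41) and fibroblast or meningeal-like (18) cells. A further 968 cells were in unnamed clusters. Motor neurons, the cells lost in this disease, could not be studied with 41 neuron-like cells in all.

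Astrocyte-like cells made up 15.5% ± 5.41 (SD, n = 4) of WT cells and 4.20% ± 1.67 (n = 4) of vehicle cells, lower by 11.3 percentage points in the vehicle group with no overlap between libraries (exact permutation p = 0.0286, adjusted p = 0.210). Oligodendrocyte precursor-like cells made up 1.20% ± 0.816 in WT and 2.38% ± 0.681 with vehicle (n = 4 each, exact permutation p = 0.0286, adjusted p = 0.210). Microglia-like cells made up 36.8% ± 15.5 in WT and 56.1% ± 3.54 with vehicle (n = 4 each, exact permutation p = 0.143, adjusted p = 0.314); WT library N8, with 173 cells kept, held 59.5% (95% exact binomial interval 51.8 to 66.9). Oligodendrocyte-like cells made up 26.8% ± 6.14 in WT and 17.7% ± 1.08 with vehicle (n = 4 each, exact permutation p = 0.0571, adjusted p = 0.251). Under the inhibitor, T or NK cell-like cells were 0.745% ± 0.263 against 1.29% ± 0.243 with vehicle (n = 4 each, exact permutation p = 0.0286, adjusted p = 0.210). Microglia-like cells made up 55.4% ± 5.16 against 56.1% ± 3.54 (n = 4 each, exact permutation p = 0.829, adjusted p = 0.958). None of the 22 comparisons passed adjustment, the smallest exact p possible being 0.0286, and shares are of cells that survived dissociation and myelin removal. No WT precursor-like cell was found among the 173 cells of N8, which allows a share of up to 2.11% (upper end of the 95% exact binomial interval).

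**Figure D1:**
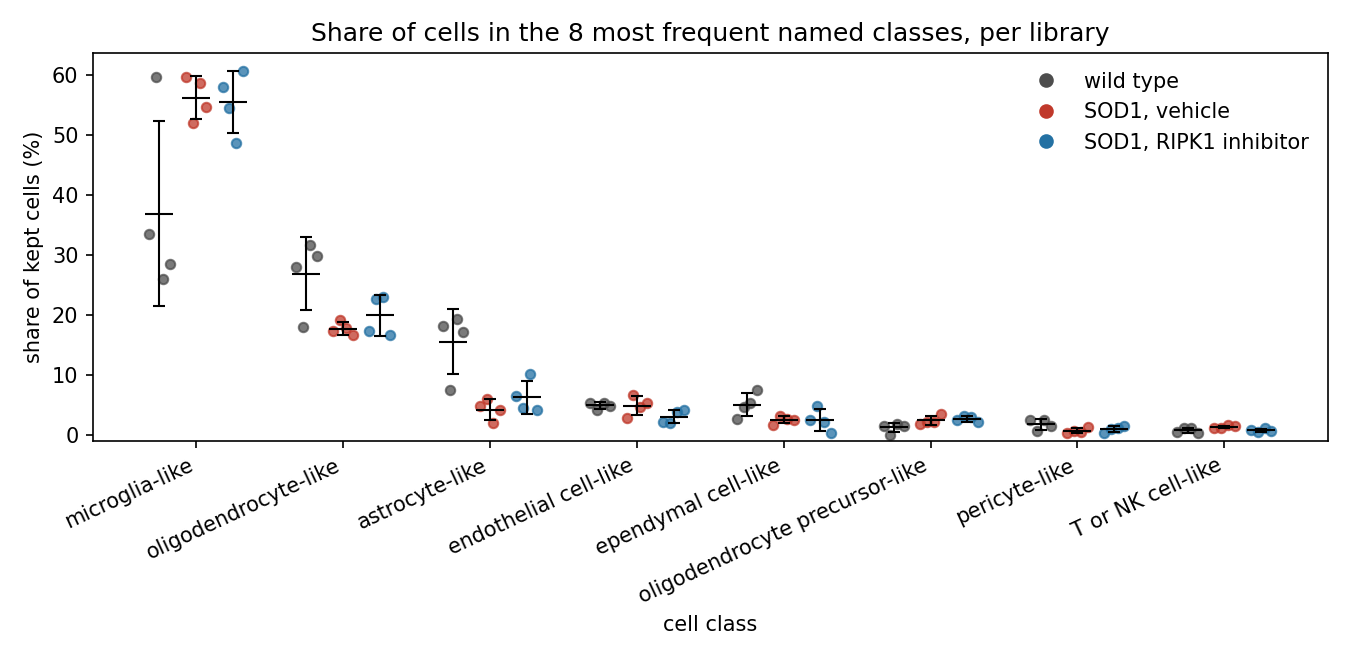
Share of kept cells (%, vertical axis) in the 8 most frequent named classes, with 1 point per library and bars for the mean and SD of 4 libraries in WT (grey), vehicle (red) and inhibitor (blue) groups. Astrocyte-like cells average 15.5% in WT and 4.20% with vehicle, and 1 WT library holds 59.5% microglia-like cells.

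Sod1, the mouse gene whose human counterpart is the transgene, was checked first (ENSMUSG00000022982, chromosome 16, 90220754 to 90226329, plus strand, GRCm38). Over all kept cells it stood at 95.2 ± 51.8 CPM in WT libraries (range 64.2 to 173), 4891 ± 1205 with vehicle (3595 to 6119.8) and 4485 ± 536 with inhibitor (3892 to 5052; SD, n = 4 each). The libraries of both SOD1 groups thus all lay above every WT library. Counts of Sod1 in the SOD1 groups can include reads of the human transgene, which has no feature of its own in the counts, so Sod1 values of these groups may not measure the mouse gene alone. In microglia the inhibitor and vehicle groups differed in Sod1 by a log2 fold change of -0.14 (SE 0.21, edgeR adjusted p = 1.00). Ripk1, the gene of the inhibited kinase (ENSMUSG00000021408, chromosome 13, 34002363 to 34037147, plus strand), stood at 30.3 ± 10.6, 37.7 ± 6.33 and 40.0 ± 4.83 CPM in the same order. In microglia its log2 fold change was 0.02 (SE 0.14, adjusted p = 0.947) between vehicle and WT and 0.09 (SE 0.13, adjusted p = 1.00) between inhibitor and vehicle, and in neither comparison did oligodendrocytes or astrocytes pass for Ripk1.

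The disease comparison in microglia asks how these resident immune cells of the cord differed between vehicle-treated SOD1 and WT mice. Apoe, a lipid carrier, rose from 1301 ± 436 to 27376 ± 4365 CPM (SD, n = 4 each; log2 fold change 4.40, SE 0.24, edgeR adjusted p = 7.48e-11). Spp1, the secreted glycoprotein osteopontin, rose from 97.5 ± 69.5 to 5113 ± 1076 CPM (log2 5.84, SE 0.49, adjusted p = 8.05e-06), and Igf1, a growth factor, from 4.57 ± 5.06 to 267 ± 44.6 CPM (log2 6.29, SE 0.34, adjusted p = 1.56e-09). Gpnmb, a transmembrane glycoprotein of phagocytes, had no UMI in WT microglia and 9294 with vehicle, at least 869-fold higher. P2ry12, a purinergic receptor of surveying microglia, fell from 1953 ± 117 to 608 ± 108 CPM (log2 -1.68, SE 0.14, adjusted p = 1.62e-08). In all, 3621 of 11210 genes changed, 1992 higher and 1629 lower. Different clusters held most of the class in the 2 groups. Clusters 4 and 0, led by Crybb1, P2ry12 and Tmem119, held 60.4% and 33.5% of WT microglia and 6.5% and 18.0% of vehicle microglia. Clusters 2, 3, 6 and 12, led in turn by Cst7 and Lyz2, Ccl4 and Ccl3, Lag3 and C1qa, and Ifit3 and Ifit2, held 30.1%, 20.1%, 15.3% and 7.5% of vehicle microglia.

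Further large rises were of Fn1 (fibronectin; log2 6.49, SE 0.76, adjusted p = 9.68e-05), Ms4a7 (a membrane protein of macrophages, also in the marker list of border macrophages; log2 6.44, SE 1.07, adjusted p = 0.00117) and Sod1 (log2 6.14, SE 0.27, adjusted p = 3.66e-11), whose counts can include transgene reads. Pf4, another marker of border macrophages, named after its values were seen, had 3 UMIs in WT and 195 with vehicle in these sums. Baiap2l2 and Ube2c, the latter a ubiquitin-conjugating enzyme of mitosis, had 2 and 3 UMIs in WT and were higher by ratios of 75.3 (95% counting interval 20.8 to 623) and 43.7 (14.9 to 213). The largest falls were of Crybb1, a crystallin expressed by microglia (log2 -2.14, SE 0.32, adjusted p = 0.000408), Gbp7 (-2.07, SE 0.18), Asb2 (-1.96, SE 0.24), Serpinf1 (-1.85, SE 0.26), the fructose transporter Slc2a5 (-1.85, SE 0.14), the kinase gene Prkca (-1.83, SE 0.20), Lrba (-1.82, SE 0.15) and Camk2n1 (-1.75, SE 0.14), each with an adjusted p of 0.000408 or less. Over its alternatives Ms4a7 ran from 3.51 with the stricter cell filter to 7.23 without N8. With the stricter cell filter Gpnmb was 4.601, below the lower bound given above, and Igf1 5.70. Fn1 was 5.43 with every library thinned and Spp1 6.83 without both N8 and N10. Baiap2l2 was 7.12 without N8 and Ube2c 6.44 without N4.

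Among the gene lists, all 21 tested disease-associated microglia genes rose, 21 also when adjusted over the list alone (median log2 3.51, also with Gpnmb at its lower bound; camera adjusted p = 1.37e-18, but adjusted p = 0.0975 with an estimated correlation). Of 14 homeostatic microglia genes, 11 fell, 1 rose and 2 did not pass (median -0.85, adjusted p = 2.70e-07, and adjusted p = 0.0290 with an estimated correlation, same counts adjusted over the list alone). P2ry13 fell by 1.50 on the log2 scale (SE 0.11), and the member that rose was Fcrls (0.82, adjusted p = 0.00030), named after its values were seen. All 12 lipid handling genes rose, also adjusted over the list alone (median 2.20, adjusted p = 6.35e-10, and adjusted p = 0.0290 with an estimated correlation), among them Nceh1, a cholesteryl ester hydrolase (2.18, SE 0.16), and Plin2, a lipid droplet coat protein (2.06, SE 0.15). Of 16 cell cycle genes 15 rose, 15 adjusted over the list alone (median 2.05, adjusted p = 8.34e-09, adjusted p = 0.222 with an estimated correlation), including Cdk1 (2.95, SE 0.33) and the centromere gene Cenpa (2.29, SE 0.26).

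Metabolic lists were higher too. Of 12 glycolysis genes 9 rose, 9 adjusted over the list alone (median 1.35, adjusted p = 1.23e-05, adjusted p = 0.228 with an estimated correlation), including Pgk1 (2.00, SE 0.13) and Pkm (1.78, SE 0.14). Of 16 oxidative phosphorylation genes 12 rose, 14 adjusted over the list alone (median 0.61, adjusted p = 2.43e-05, adjusted p = 0.432 with an estimated correlation), with the cytochrome c oxidase genes Cox6c (0.90, SE 0.13) and Cox4i1 (0.92, SE 0.13). Of 17 cholesterol synthesis genes 10 rose, 10 adjusted over the list alone (median 0.57, adjusted p = 0.000274, adjusted p = 0.228 with an estimated correlation), with Cyp51 (0.99, SE 0.16) and Insig1, a brake on sterol synthesis (1.01, SE 0.20). Of 18 lysosome genes 13 rose, 13 adjusted over the list alone with 1 lower (median 0.71, adjusted p = 2.25e-05, adjusted p = 0.279 with an estimated correlation), with the hydrolase gene Gusb (1.08, SE 0.13) and the cholesterol transfer gene Npc2 (1.24, SE 0.16).

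Immune lists were higher as well. Of 18 interferon-stimulated genes 10 rose, 10 adjusted over the list alone (median 1.22, adjusted p = 0.000309, adjusted p = 0.538 with an estimated correlation), with Ifi27l2a (2.83, SE 0.47) and Ifi204 (1.41, SE 0.23). Of 13 antigen presentation genes 9 rose, 11 adjusted over the list alone (median 1.18, adjusted p = 7.79e-05, adjusted p = 0.431 with an estimated correlation), with Cd74, the invariant chain (2.64, SE 0.32), and H2-Ab1 (2.03, SE 0.31). The list of NF-kB and cytokine genes did not pass (6 of 16 rose and 2 fell, as also adjusted over the list alone; median 0.43, adjusted p = 0.245). The chemokine Ccl2 rose (2.05, SE 0.33) and Il6 (-1.76, SE 0.28) and Icam1 (-0.42, SE 0.13, adjusted p = 0.019) fell. Icam1 did not pass without A2 (adjusted p = 0.0590), A5 (0.0632), N10 (0.0610) or both N8 and N10 (0.129), nor with the stricter cell filter (0.0597). The RIPK1 and cell death list did not pass either (median -0.14, adjusted p = 0.172), with 4 of 15 members lower, 4 adjusted over the list alone. These were Casp8, the protease that cleaves RIPK1 (-0.47, SE 0.10), its regulator Cflar (-0.40, SE 0.11), and, named after their values were seen, Birc3 (-0.67) and Gsdmd (-0.41). Casp8 did not pass with every library thinned (adjusted p = 0.0541), nor Birc3 thinned (0.318) or without N4 (0.131), nor Gsdmd without A2 (0.0637) or N9 (0.0515) or with no filter on low genes (0.0572). Of 16 immediate early and dissociation genes 6 rose and 2 fell, 7 and 2 adjusted over the list alone (median 0.63, adjusted p = 0.0896, and 0.0246 without N10). Atf3 (2.88, SE 0.24) and Ier3 (2.19, SE 0.36) rose, and Btg2 (-0.73) and Klf2 (-1.18), named after their values were seen, fell. Klf2 did not pass without N4 (adjusted p = 0.0918), A2 (0.0992), A5 (0.0721), N9 (0.136), A7 (0.104) or A11 (0.0651), nor with no filter on low genes (0.107) or the stricter cell filter (0.0624).

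Lists written for other cells held genes that microglia also express. Vim, an intermediate filament gene (4.08, SE 0.19), Cd44 (2.72, SE 0.22) and, named after its values were seen, the complement gene C3 (4.19) made up the 3 of 6 reactive astrocyte genes that rose. S100a10 fell (-0.89), with the same counts adjusted over the list alone (list adjusted p = 0.0116, adjusted p = 0.133 with an estimated correlation). It did not pass without N4 (adjusted p = 0.104), A2 (0.0633), N9 (0.0794), A7 (0.0689), A11 (0.0624) or both N8 and N10 (0.0777), nor with a term for library numbers (0.0747), the stricter cell filter (0.0629) or every library thinned (0.0577). Of 9 disease-associated oligodendrocyte genes 5 rose and 1 fell, as also adjusted over the list alone (adjusted p = 0.0138, adjusted p = 0.431 with an estimated correlation), led by Anxa2 (4.03, SE 0.21) and the cell cycle inhibitor gene Cdkn1a (2.72, SE 0.20). Endothelial activation genes (2 of 5 rose and 1 fell, 3 and 1 adjusted over the list alone, adjusted p = 0.245) included Ch25h, a cholesterol hydroxylase (5.05, SE 0.60, and 7.51 without N4). Blood-brain barrier genes (2 of 6 rose and 1 fell, as adjusted over the list alone, adjusted p = 0.669) included the glucose transporter gene Slc2a1 (1.31, SE 0.14) and Tjp1 (-0.70, SE 0.16). For the latter list the median was -0.03 and the mean 0.05. Marker lists of other cells were lower in the microglial sums, passing with fry but not with camera. Oligodendrocyte markers had a median of -0.73 (4 of 8 fell, 5 over the list alone, camera adjusted p = 0.0617, fry 0.0276). Astrocyte markers stood at -0.82 (3 of 7, list alone 4, 0.0617 and 0.0406). Neuron markers stood at -1.54 (2 of 4, list alone 3, 0.109 and 0.0276). Between library numbers 1 to 6 and 7 to 12, 3041 of 11210 genes differed. Within 1 to 6 alone 3020 changed between vehicle and WT and within 7 to 12 alone 2548, including 2661 and 2358 of the 3621. With a term for the sets 4521 changed, 3607 of them among the 3621.

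**Figure D2:**
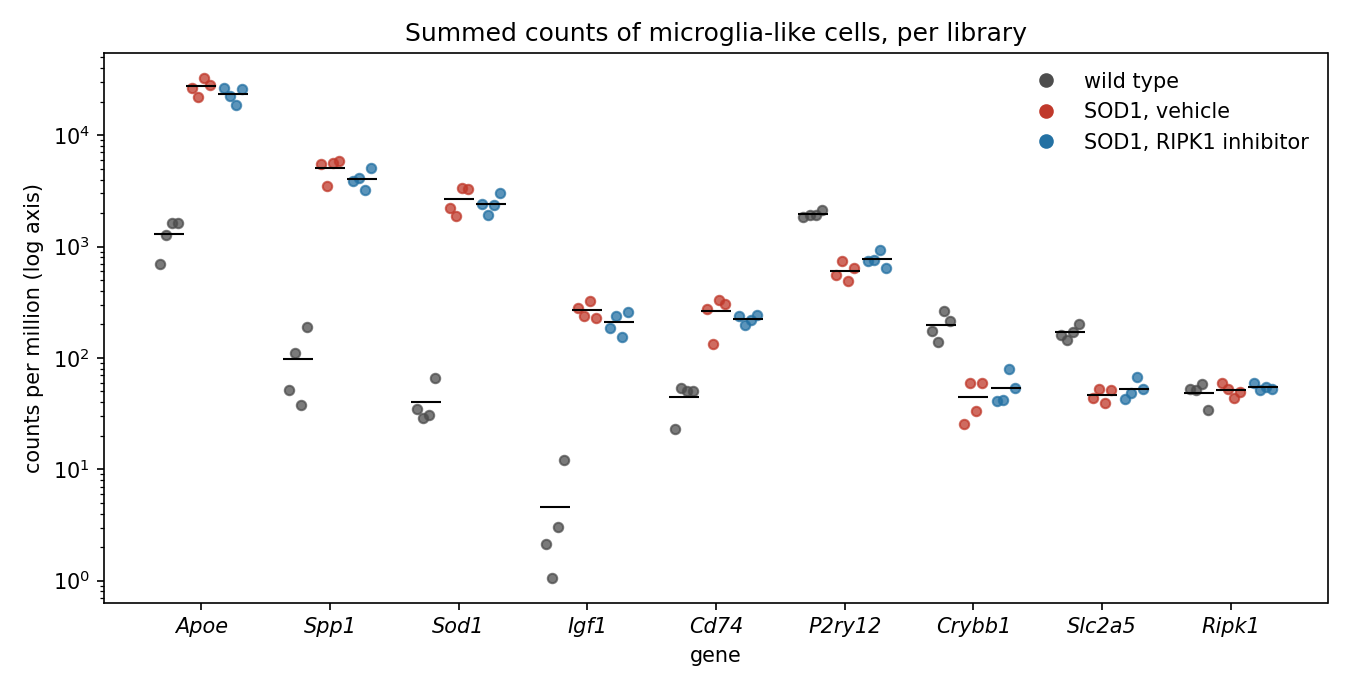
Summed counts of microglia-like cells in CPM (vertical log axis) for 9 genes, with 1 point per library and a line at each group's mean, in WT (grey), vehicle (red) and inhibitor (blue) libraries. All SOD1 libraries lie above all WT libraries for Apoe, Spp1, Sod1, Igf1 and Cd74 and below them for P2ry12, Crybb1 and Slc2a5, and Ripk1 overlaps in all 3 groups.

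The treatment comparison in microglia asks whether the inhibitor changed these cells in SOD1 mice. No single gene passed with edgeR's quasi-likelihood test (0 of 11210; 294 had an unadjusted p under 0.05), nor with DESeq2 (0, 196 unadjusted) or limma-voom (0, 338 unadjusted). P2ry12 was 772 ± 122 CPM with inhibitor and 608 ± 108 with vehicle (SD, n = 4 each; log2 0.34, SE 0.14). Gpnmb was 229 ± 70.6 and 319 ± 82.2 CPM (log2 -0.48, SE 0.24; adjusted p = 1.00 for both). The smallest p-value belonged to E230001N04Rik (log2 -1.06, SE 0.24), with an adjusted p of 0.0444 with no filter on low genes. Within library numbers 1 to 6 alone 1 gene passed, Gm42047 (log2 1.90, SE 0.23, adjusted p = 0.00197), named after its values were seen, which stood at 0.50 over all libraries (adjusted p = 1.00). Within 7 to 12 alone 0 genes passed with edgeR (520 unadjusted). Next came the cyclin gene Ccnd3 (-0.55, SE 0.13), Mical2 (-0.86, SE 0.21), Cytip (-0.82, SE 0.20) and the chemokine gene Cxcl14 (-0.49, SE 0.13), none of which passed. In simulation the test recovered 80.6% of 2-fold and 50.7% of 1.5-fold changes made together, so smaller or isolated ones may go undetected.

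As groups, 6 of the 17 lists passed at the preset correlation, none with an estimated one, and no member passed over all genes. Disease-associated microglia genes were lower as a list (median -0.19, camera adjusted p = 0.000216, adjusted p = 0.431 with an estimated correlation). Homeostatic genes were higher (median 0.09, adjusted p = 0.00103, adjusted p = 0.133 with an estimated correlation), including the transcription factor gene Sall1 (0.29, SE 0.12). Lipid handling genes were lower as a list (median -0.20, adjusted p = 0.00378, adjusted p = 0.222 with an estimated correlation), with Fabp3 at -0.52 (SE 0.22). Antigen presentation genes were lower (median -0.22, adjusted p = 0.0138, adjusted p = 0.538 with an estimated correlation), with H2-Eb1 at -0.79 (SE 0.29). Cell cycle genes were lower (median -0.14, adjusted p = 0.0295, adjusted p = 0.538 with an estimated correlation), with Cdk1 at -0.38 (SE 0.20). Endothelial activation genes were higher (median 0.27, adjusted p = 0.0221, adjusted p = 0.277 with an estimated correlation), with Icam1 at 0.27 (SE 0.12). Adjusted over the list alone, no member of these 6 lists passed; in the disease-associated oligodendrocyte list 1 of 9 did, Sgk1 (-0.38, SE 0.11). Interferon-stimulated genes (median -0.36, adjusted p = 0.0550) included Irf7 at -0.68 (SE 0.53) and Zbp1 at -0.51 (SE 0.38), which stood at 0.22 and 0.11 without vehicle library A7.

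Single libraries decided several of these list results. The interferon list was higher with inhibitor without A7 (adjusted p = 0.00346) and lower without A2 (0.000160), A5 (0.00410), A11 (0.00508), B3 (0.00306) or B8 (0.0478). The disease-associated microglia list did not pass without A7 (adjusted p = 0.224), the lipid handling list without B8 (0.168) and the antigen presentation list without A7 (0.956, in the other direction), B4 (0.205) or B8 (0.196). The cell cycle list did not pass without A2 (adjusted p = 0.146), A7 (0.342), B3 (0.338), B4 (0.150) or B8 (0.0683), nor the endothelial activation list without A2 (0.110), A5 (0.0796), A11 (0.0654), B3 (0.0661) or B12 (0.0616). The homeostatic list passed without each library in turn. Glycolysis genes passed as a list, lower, without A2 (adjusted p = 0.0150), A5 (0.00364) or B12 (0.00107), lysosome genes without B3 (0.0497) and oxidative phosphorylation genes without B12 (0.0404).

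The lists of NF-kB (median -0.05, mean 0.01, test direction up, adjusted p = 0.412), RIPK1 and cell death (median 0.05, adjusted p = 0.172), and lysosome genes (-0.01, adjusted p = 0.559) did not pass. Nor did cholesterol synthesis (-0.01, adjusted p = 0.547), glycolysis (-0.12, adjusted p = 0.0616), oxidative phosphorylation (-0.05, adjusted p = 0.562) and immediate early genes (-0.07, adjusted p = 0.165). Reactive astrocyte (-0.02, adjusted p = 0.542), disease-associated oligodendrocyte (-0.06, adjusted p = 0.172) and blood-brain barrier genes (median -0.01, mean 0.02, test direction down, adjusted p = 0.720) did not pass either. Named members of these lists that did not pass over all genes were Relb (0.19, SE 0.13), Birc3 (0.20, SE 0.17), Tradd (-0.16, SE 0.17, and 0.471 with every library thinned), Lamp2 (-0.08, SE 0.11), Sc5d (-0.26, SE 0.15), Pgk1 (-0.21, SE 0.11), Sdha (0.12, SE 0.10) and Klf4 (-0.52, SE 0.16). Marker lists of oligodendrocytes (median 0.11, adjusted p = 0.286) and of astrocytes (median -0.12, mean 0.07, test direction up, adjusted p = 0.425) in the microglial sums did not pass.

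Against WT, microglia under the inhibitor differed in 3061 of 11210 genes, 1757 higher and 1304 lower. Apart from Sod1 (6.00, SE 0.27, with possible transgene reads), the largest rises were of Fn1 (6.61, SE 0.75), Igf1 (5.93, SE 0.34), Ms4a7 (5.54, SE 1.17), Spp1 (5.51, SE 0.49) and Gpnmb, at least 624-fold higher. Baiap2l2 and Ube2c were higher by ratios of 63.5 (95% counting interval 17.5 to 526) and 44.8 (15.2 to 218). The largest falls were of Crybb1 (-1.87, SE 0.32), Slc2a5 (-1.66, SE 0.14), Khdrbs3 (-1.59, SE 0.23), Lrba (-1.53, SE 0.15), Mtss1 (-1.52, SE 0.19), the platelet glycoprotein gene Gp9 (-1.52, SE 0.24), Itga9 (-1.48, SE 0.17) and Gbp7 (-1.48, SE 0.18), each with an edgeR adjusted p of 0.00119 or less. Ms4a7 ran from 2.68 with the stricter cell filter to 6.33 without N8. Gpnmb was 4.20 and Igf1 5.33 with the stricter cell filter, Fn1 5.602 with every library thinned and Spp1 6.50 without both N8 and N10. Baiap2l2 was 6.85 without N8 and Ube2c 6.26 without N4. Clusters 0, 2, 3 and 6 held 24.2%, 22.9%, 19.1% and 17.1% of inhibitor microglia, and cluster 4 held 8.8%.

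Across genes, the change with inhibitor was set against the change with disease, both of which contain the vehicle libraries. The covariance of the 2 log2 fold changes over 11210 genes was -0.0724 (Pearson's r = -0.42; genes are not independent replicates). It was -0.0210 ± 0.0009 (SD, 100 simulations, r = -0.40) for simulated unchanged groups sharing the same vehicle libraries, a difference of -0.0514; genes were drawn independently, so shifts of whole libraries are not in that SD. With the vehicle libraries divided so that none served both contrasts, the covariance was negative in 6 of 6 divisions, with a mean of -0.0509 and a range from -0.0994 to -0.0076. It ranged from -0.116 without A5 to -0.0495 without A7.

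In oligodendrocytes, the myelinating cells, the disease comparison called 135 of 9958 genes, 107 higher and 28 lower. Serpina3n, a secreted protease inhibitor, rose from 25.2 ± 15.8 to 377 ± 254 CPM (SD, n = 4 each; log2 4.33, SE 0.74, edgeR adjusted p = 0.0203). The complement gene C4b rose from 40.8 ± 35.3 to 292 ± 140 CPM (log2 3.32, SE 0.62, adjusted p = 0.0321) and the transcription factor gene Cebpd from 12.3 ± 2.05 to 96.2 ± 45.6 CPM (log2 2.86, SE 0.35, adjusted p = 0.000687). Sod1, with possible transgene reads, stood higher by a log2 fold of 6.82 (SE 0.61, and 7.77 without N10). Creb5 (-0.91, SE 0.15), Rin2 (-1.01, SE 0.22), the semaphorin gene Sema4c (-0.95, SE 0.18) and the adhesion gene Nectin1 (-0.89, SE 0.19) fell. Serpina3n did not pass without N4 (adjusted p = 0.0813) or N9 (0.0959), and C4b without N4 (0.111), A2 (0.0584), N9 (0.148), N10 (0.120), A7 (0.0666) or A11 (0.0682). Rin2 did not pass without N9 (0.0773) or with doublets kept (0.132), nor Nectin1 without N4 (0.0846), A2 (0.0502), N10 (0.0597), A7 (0.0601) or A11 (0.0820). Without both N8 and N10, Serpina3n (adjusted p = 0.0825), C4b (0.0546), Sema4c (0.0513) and Nectin1 (0.117) did not pass. Clusters 1, 7 and 10 held 57.6%, 26.4% and 13.4% of WT oligodendrocytes and 44.3%, 19.7% and 12.5% of vehicle ones; cluster 14, led by Serpina3n and C4b, held 0.8% and 18.0%.

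By lists, 4 of 12 disease-associated oligodendrocyte genes rose in oligodendrocytes, 10 adjusted over the list alone (median 1.31, camera adjusted p = 2.42e-12, adjusted p = 0.0339 with an estimated correlation): Serpina3n, C4b, Anxa2 (2.90, SE 0.56) and Fos (3.91, SE 0.66). Anxa2 did not pass without N4 (0.118) or N9 (0.119), nor Fos without N4 (0.0785), N9 (0.0716) or both N8 and N10 (0.0970). Of 5 reactive astrocyte genes 2 rose, 4 adjusted over the list alone (median 2.17, adjusted p = 8.97e-07, adjusted p = 0.031 with an estimated correlation), Serpina3n and Gfap (2.17, SE 0.29). Astrocyte markers as a whole had a median of 0.02 (adjusted p = 0.465). Cholesterol synthesis genes were lower as a list (median -0.45, adjusted p = 8.26e-13, adjusted p = 0.107 with an estimated correlation), with Hmgcs1 at -0.64 (SE 0.16, adjusted p = 0.0449). Hmgcs1 did not pass without N4 (adjusted p = 0.0882), N8 (0.158), A2 (0.171), A7 (0.121), A11 (0.0844) or both N8 and N10 (0.260), nor with only the 2 groups (0.0723), a minimum of 50 cells (0.158) or a term for library numbers (0.126). Immediate early genes were higher as a list (2 of 9 rose, 4 adjusted over the list alone with 1 lower; median 0.47, adjusted p = 0.000164, adjusted p = 0.112 with an estimated correlation), with Junb at 3.22 (SE 0.44). Antigen presentation genes were higher as a list (median 1.86, adjusted p = 2.79e-05, adjusted p = 0.107 with an estimated correlation), with B2m at 2.01 (SE 0.48) and H2-T23 at 2.59 (SE 0.69). Interferon-stimulated genes were too (median 0.42, adjusted p = 0.010, adjusted p = 0.107 with an estimated correlation), with Bst2 at 2.78 (SE 0.72) and Ifi27l2a at 2.71 (SE 0.80). In both lists 0 of 5 members passed over all genes, and 4 and 2 did adjusted over the list alone. Of these, B2m passed without N8 (0.0469) or A5 (0.0470), and Bst2 (0.00802) and H2-T23 (0.0163) passed without A5.

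Disease-associated microglia genes were also higher in the oligodendrocyte sums, 4 of 12 over all genes and 12 adjusted over the list alone (median 0.61, adjusted p = 2.55e-15, adjusted p = 0.0339 with an estimated correlation). Spp1 had 0 UMIs in WT and 73 with vehicle, at least 37.8-fold higher. Lyz2 stood at 0.367 ± 0.535 and 9.98 ± 2.12 CPM (SD, n = 4 each; log2 3.92, SE 0.51, and 5.12 without N9), and Trem2 (2.48) and Apoe (0.87), named after their values were seen, rose. With doublets kept Spp1 (adjusted p = 0.459), Lyz2 (0.0715) and Trem2 (0.0513) did not pass. Trem2 did not pass without N9 (0.0778), A11 (0.0508, at 1.82) or both N8 and N10 (0.0750) or with limma-voom (0.0665) either. Nor did Apoe without N4 (0.0932), N8 (0.0653), A2 (0.0616), A7 (0.0880) or both N8 and N10 (0.063), with only the 2 groups (0.0615) or with a minimum of 50 cells (0.0653). Microglia markers in the same sums were higher (median 0.75, adjusted p = 0.000117, adjusted p = 0.264 with an estimated correlation). RNA of microglia, by those markers, made up 0.146% ± 0.048 of WT and 0.458% ± 0.360 of vehicle oligodendrocyte counts (SD, n = 4 each), and 0.278% ± 0.020 (n = 3) of the latter without A11, which held 0.997%. Precursor markers were higher too (median 1.30, adjusted p = 0.0214, adjusted p = 0.264 with an estimated correlation), with Lhfpl3, named after its values were seen, at 2.04 (adjusted p = 0.00709, and 0.0518 without N9).

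Between library numbers 1 to 6 and 7 to 12, 2855 of 9958 oligodendrocyte genes differed. With a term for these sets 357 genes changed between vehicle and WT in oligodendrocytes, 213 higher and 144 lower, including 131 of the 135. Within numbers 1 to 6 alone 147 changed and within 7 to 12 alone 373, including 86 and 105 of the 135, and all 135 kept their direction in both. Without both small WT libraries, N8 and N10, 60 changed. Lysosome (median 0.14, adjusted p = 0.0852), glycolysis (-0.05, adjusted p = 0.250), oxidative phosphorylation (0.08, adjusted p = 0.252), and RIPK1 and cell death lists (0.03, adjusted p = 0.501) did not pass in oligodendrocytes. Nor did lipid handling (0.08, adjusted p = 0.478), cell cycle (0.30, adjusted p = 0.196), blood-brain barrier (-0.40, adjusted p = 0.150), homeostatic microglia (0.64, adjusted p = 0.443) and NF-kB lists (median -0.41, mean 0.12, test direction down, adjusted p = 0.443). Of 3 tested NF-kB genes 1 rose, the inhibitor gene Nfkbia (1.57, adjusted p = 0.0160), named after its values were seen. It did not pass without N10 (adjusted p = 0.0523) or A7 (0.0694).

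Under the inhibitor, 2 of 9958 genes changed in oligodendrocytes, both lower. Tma16, a gene of ribosome assembly (ENSMUSG00000025591, chromosome 8, 66473118 to 66486530, minus strand), fell from 159.9 ± 19.7 CPM with vehicle to 70.8 ± 8.57 (SD, n = 4 each; log2 -1.19, SE 0.14, edgeR adjusted p = 0.000416). Ada, adenosine deaminase, named after its values were seen, fell from 20.1 ± 1.69 to 7.82 ± 2.06 CPM (log2 -1.31, SE 0.21, adjusted p = 0.0173). Both had risen with disease, Tma16 by 1.72 (SE 0.15, adjusted p = 1.71e-06) and Ada by 1.68 (SE 0.22, adjusted p = 0.000205), and against WT the inhibitor group stood at 0.52 (adjusted p = 0.166) and 0.37 (adjusted p = 0.847). Both comparisons contain the same 4 vehicle libraries, so opposite signs are expected with no effect: of the 32 genes with the smallest p with inhibitor 31 ran opposite to the disease change, and 31.03 on average in 100 simulations of unchanged groups. DESeq2 called 7 genes and limma-voom 2, and 379 had an unadjusted p under 0.05. The list of cholesterol synthesis genes was higher (median 0.26, camera adjusted p = 9.33e-07, adjusted p = 0.228 with an estimated correlation), with Sqle, squalene epoxidase, at 0.46 (SE 0.15) and Lss at 0.57 (SE 0.21). Immediate early genes were lower (median -0.46, adjusted p = 0.000814, adjusted p = 0.153 with an estimated correlation), with the phosphatase gene Dusp1 at -0.74 (SE 0.19) and Nr4a1 at -0.66 (SE 0.27). Antigen presentation genes were lower as a list (median -0.61, adjusted p = 0.0191, adjusted p = 0.248 with an estimated correlation), with B2m at -0.67 (SE 0.42) and H2-T23 at -1.07 (SE 0.58). So were cell cycle genes (median -0.41, adjusted p = 0.0434, adjusted p = 0.165 with an estimated correlation), with Hmgb2 at -0.60 (SE 0.21) and Mcm2 at -0.41 (SE 0.34). No member of these 4 lists passed over all genes; adjusted over the list alone, 0 of 17, 1 of 9, 0 of 5 and 1 of 3 did. The other 12 lists had adjusted p-values from 0.0693 to 0.784, the lowest being of NF-kB genes, whose 3 tested members passed adjusted over the list alone, 2 higher and 1 lower. Precursor markers were lower (median -0.70, adjusted p = 0.0152, adjusted p = 0.264 with an estimated correlation). With a term for library numbers, 32 genes changed, 24 lower and 8 higher, Tma16 and Ada among them. Within numbers 1 to 6 alone 43 changed, both among them, and within 7 to 12 alone 6, Tma16 but not Ada among them. Without A2, B4 or A11 1 gene passed, Tma16, with Ada at an adjusted p of 0.0577, 0.192 and 0.13, and without B3 or A7 4 genes did.

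In astrocytes, the disease comparison rested on 3 WT and 3 vehicle libraries and called 30 of 6988 genes, 22 higher and 8 lower. Timp1, an inhibitor of metalloproteinases, had 2 UMIs in WT and 22 with vehicle, a ratio of 33.8 (95% counting interval 8.32 to 297). Tm4sf1 rose by a log2 fold of 4.32 (SE 0.67, edgeR adjusted p = 0.000238), and Aebp1 (5.37, SE 0.80, adjusted p = 0.0118), Tagln2 (4.43, SE 0.96, adjusted p = 0.0359) and Sod1 (5.50, SE 0.25, with possible transgene reads) also rose. Olig2, a transcription factor gene, fell from 183 ± 59.0 to 55.8 ± 18.4 CPM (SD, n = 3 each; log2 -1.65, SE 0.29, adjusted p = 0.00165), as did Pmepa1 (-1.55, SE 0.34), Pid1 (-1.35, SE 0.29) and Fdps (-1.21, SE 0.29). All 11 reactive astrocyte genes were higher, 3 over all genes and 11 adjusted over the list alone (median 2.52, camera adjusted p = 2.68e-21, adjusted p = 0.0193 with an estimated correlation): Timp1, Tm4sf1 and, named after its values were seen, C3 (2.01). Of 16 cholesterol synthesis genes 3 fell, 10 adjusted over the list alone (median -0.70, adjusted p = 3.00e-12, adjusted p = 0.0781 with an estimated correlation): Fdps, Insig1 (-1.04, SE 0.24) and Dhcr7 (-1.15, SE 0.27). Disease-associated oligodendrocyte genes (2 of 9 rose, 4 adjusted over the list alone; median 1.40, adjusted p = 2.77e-05, adjusted p = 0.0276 with an estimated correlation) included C4b (1.99, SE 0.36) and Fos (2.70, SE 0.65). Clusters 5 and 18, the latter led by Gfap and A2m, held 94.8% and 5.2% of WT astrocytes and 81.9% and 18.1% of vehicle ones. The count was 19 without A2, 17 without N9, 18 without N10 and 53 without A5. With a term for library numbers 44 genes changed, 21 higher and 23 lower, 22 of them among the 30.

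Most of these astrocyte calls ended when some library was left out. Tm4sf1 did not pass without A5 (adjusted p = 0.0516), nor Aebp1 without N4 (0.157) or N9 (0.109), nor C3 without N4 (0.0613). C4b did not pass without N4 (0.157), A5 (0.0516), N9 (0.109) or A11 (0.0539), nor Fos without N4 (0.157), A2 (0.300), N9 (0.235) or A11 (0.100). Tagln2 did not pass without N4 (0.349), A2 (0.217), N9 (0.326), N10 (0.118) or A11 (0.126), nor Pmepa1 without A2 (0.114), N10 (0.118) or A11 (0.172). Pid1 did not pass without N4 (0.0553), A2 (0.0573), A5 (0.0848) or A11 (0.0729). Among the cholesterol genes, Fdps did not pass without A2 (0.179), N9 (0.235), N10 (0.118) or A11 (0.216), Insig1 without A2 (0.162), A5 (0.125), N9 (0.104) or N10 (0.113) and Dhcr7 without N4 (0.0553), A2 (0.162), A5 (0.125) or N10 (0.136). Sod1, Olig2 and Timp1 passed without each library in turn, but Olig2 and Timp1 not under every other setting. The stricter cell filter ended the calls of Olig2 (adjusted p = 0.3465), Tm4sf1 (0.923), Aebp1 (0.391), Tagln2 (0.151), C3 (0.991), Fos (0.274), Pmepa1 (0.412), Pid1 (0.118), Fdps (0.688), Insig1 (0.557) and Dhcr7 (0.274). Limma-voom ended those of Timp1 (0.0791), Tm4sf1 (0.0548), Aebp1 (0.0988), Tagln2 (0.513), Pmepa1 (0.121) and Fdps (0.133), and DESeq2 those of Fdps (0.105) and Dhcr7 (0.0834). The term for library numbers ended those of Aebp1 (0.0743), Tagln2 (0.0542), Fdps (0.0542) and C4b (0.168). A minimum of 50 cells ended those of Tagln2 (0.101), Fdps (0.0939), Insig1 (0.09005), Dhcr7 (0.09005) and Fos (0.146). Aebp1 (0.300), Pmepa1 (0.268) and Fos (0.321) did not pass with doublets kept, nor Tagln2 (0.197) with the floor of 10 CPM on low genes. Over all alternatives the log2 fold change ran from 4.07 to 7.47 for Timp1, 3.59 to 5.72 for Tm4sf1, 3.60 to 6.08 for Aebp1, 2.43 to 5.46 for Tagln2 and 1.54 to 3.38 for Fos.

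Disease-associated microglia genes were also higher as a list in astrocytes with disease (median 0.61, adjusted p = 1.17e-06, adjusted p = 0.0781 with an estimated correlation), with Ctsb at 0.74 (SE 0.23) and Lpl at 2.40 (SE 0.67). Interferon-stimulated genes were too (median 1.01, adjusted p = 0.0155, adjusted p = 0.445 with an estimated correlation), with Ifitm3 at 3.44 (SE 0.87) and Bst2 at 1.00 (SE 0.46). Over all genes 0 of 12 and 0 of 5 members passed, and 6 and 1 did adjusted over the list alone. Ifitm3 passed without A2 (adjusted p = 0.0196) or A5 (1.45e-07). RNA of microglia made up 0.212% ± 0.063 of WT and 0.332% ± 0.174 of vehicle astrocyte counts (SD, n = 3 each). Oligodendrocyte markers had a median of 1.08 (adjusted p = 0.725) and astrocyte markers of 0.13 (adjusted p = 0.0417, adjusted p = 0.161 with an estimated correlation) in these sums. Antigen presentation (median 0.10, adjusted p = 0.140), lysosome (0.21, adjusted p = 0.115), oxidative phosphorylation (0.06, adjusted p = 0.747) and immediate early lists (median -0.25, mean 0.69, test direction up, adjusted p = 0.684) did not pass. Nor did homeostatic microglia (-0.03, adjusted p = 0.747), lipid handling (0.03, test direction down, adjusted p = 0.991), RIPK1 and cell death (-0.18, adjusted p = 0.881), glycolysis (0.00, adjusted p = 0.991) and blood-brain barrier lists (0.10, adjusted p = 0.880).

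Under the inhibitor, 1 of 6988 astrocyte genes changed: Hr, the nuclear corepressor gene hairless (ENSMUSG00000022096, chromosome 14, 70552212 to 70573548, plus strand), fell from 104 ± 3.39 CPM (SD, n = 3) to 32.7 ± 10.1 (n = 4; log2 -1.68, SE 0.32, edgeR adjusted p = 0.0242). DESeq2 called 0 genes (145 at an unadjusted p under 0.05) and limma-voom 2. Hr stood at 1.03 (SE 0.27, adjusted p = 0.0785) between vehicle and WT, and did not pass under the inhibitor without A5 (adjusted p = 0.417), B4 (0.166), A11 (0.171) or B8 (0.207), nor with DESeq2 (0.145), the stricter cell filter (0.517) or doublets kept (0.0692). Interferon-stimulated genes were higher as a list (median 0.89, camera adjusted p = 0.00208, adjusted p = 0.405 with an estimated correlation), with Bst2 at 1.18 (SE 0.40) and Ifit3 at 0.89 (SE 0.36), which turned to -0.862 and -1.604 with the looser cell filter. Reactive astrocyte genes were too (median 0.57, adjusted p = 0.0059, adjusted p = 0.405 with an estimated correlation), with C3 at 1.29 (SE 0.32) and Tm4sf1 at 0.92 (SE 0.43), the latter -0.562 with the stricter cell filter. Over all genes 0 of 5 and 0 of 11 members of these lists passed, and 2 and 1 did adjusted over the list alone. The cholesterol synthesis list did not pass (median -0.11, test direction up, adjusted p = 0.881), and the adjusted p-values of the 12 lists not passing ran from 0.278 to 0.881.

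**Figure D3:**
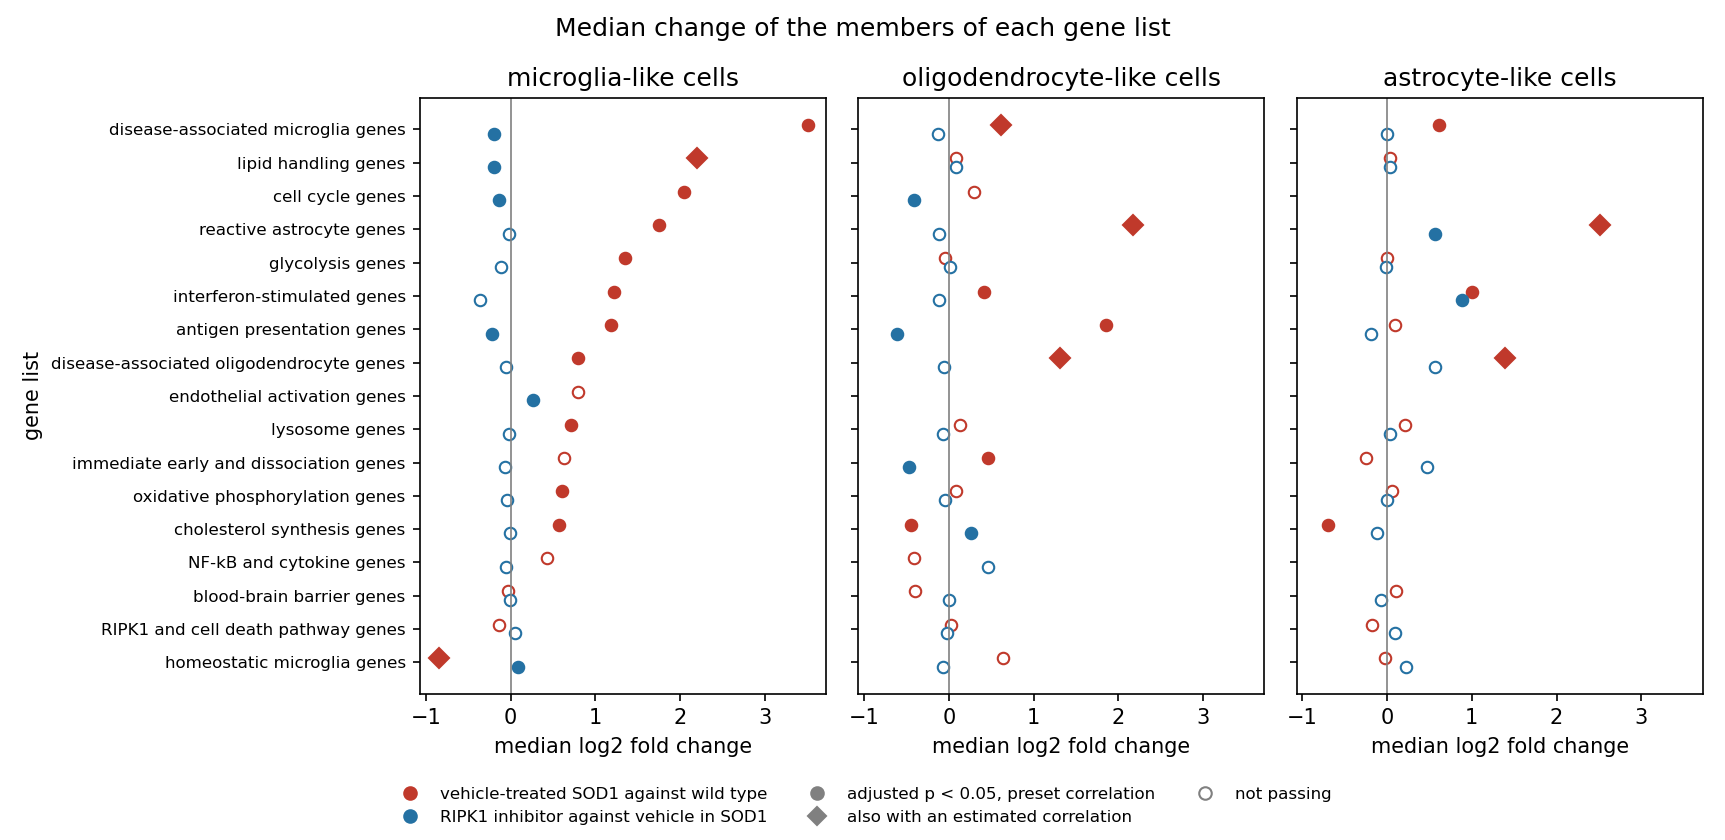
Median log2 fold change (horizontal axis) of the tested members of each gene list (vertical axis) in microglia-like, oligodendrocyte-like and astrocyte-like cells, for vehicle against WT (red) and inhibitor against vehicle (blue); filled circles passed camera's preset correlation, diamonds also an estimated one, and open circles did not pass. Disease medians in microglia reach 3.51 for disease-associated genes, while inhibitor medians there lie between -0.36 and 0.27.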

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

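The comparisons of list scores between cell classes and the tests of microglial RNA in the sums of other cells were chosen after the results were seen.

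In 32 of 461 groups of 4 libraries (6.9%), 1 library stood apart from the other 3 by a gap of more than 0.829 of the group's range, where chance gives about 1 in 20. In WT microglia, library N10 lay above the others for Sod1 (66.4 CPM, others 28.8 to 34.6), Insig1 (13.3, others 8.52 to 8.66), Vim (21.7, others 9.33 to 10.65), Cdkn1a (19.3, others 9.59 to 10.66) and H2-Aa (2.41, others 0 to 0.377). N9 lay above the others for Ifi27l2a (93.8 CPM, others 34.1 to 39.8), Fcrls (937 CPM, others 729 to 756) and Atp6v0d2 (0.377 CPM, others 0), and below them for Zbp1 (3.01 CPM, others 6.035 to 6.39). N4 was lowest for Cd74 (23.2 CPM, others 50.5 to 53.3).

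In vehicle microglia, A7 was above the others for Zbp1 (43.5 CPM, others 10.6 to 14.2), Irf7 (68.0 CPM, others 11.05 to 17.5) and Fabp3 (91.4 CPM, others 42.1 to 48.2), and below them for Btg2 (91.6 CPM, others 111 to 113.7). A5 was lowest for Spp1 (3517 CPM, others 5494 to 5864) and Slc2a1 (48.4 CPM, others 55.3 to 56.4), and A11 highest for Sc5d (39.3 CPM, others 26.4 to 28.3). In inhibitor microglia, B8 was highest for Camk2n1 (82.3 CPM, others 56.8 to 59.9) and S100a10 (14.7 CPM, others 6.185 to 6.67). B12 was lowest for Sall1 (119.5 CPM, others 152.5 to 154.3) and Tef (20.7 CPM, others 26.3 to 27.25) and highest for Tpi1 (322 CPM, others 244.7 to 256.3).

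In oligodendrocytes, WT library N10 was highest for Sod1 (234.6 CPM, others 45.5 to 56.3) and lowest for Rin2 (16.9 CPM, others 22.4 to 23.3). N8 was highest for C4b (93.1 CPM, others 19.1 to 30.6), B2m (48.5 CPM, others 15.1 to 19.1) and Lhfpl3 (3.88 CPM, others 1.84 to 1.955), and N9 lowest for Trem2 (1.46 CPM, others 1.94 to 2.01). Vehicle library A7 was highest for C4b (499 CPM, others 201.7 to 250.2) and Ifi27l2a (73.4 CPM, others 9.20 to 18.3). Inhibitor library B12 was highest for Arrdc2 (119.7 CPM, others 80.3 to 83.8) and B4 for Zbtb16 (43.2 CPM, others 30.25 to 30.7).

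Effects on mean list scores, in log2(CPM + 1), went opposite ways in microglia and oligodendrocytes, with an exact permutation p under 0.05 for the difference, for 5 lists. With disease, homeostatic microglia genes differed by -1.14 between the classes (-0.792 in microglia, 0.348 in oligodendrocytes). Cholesterol synthesis genes differed by 1.065 (0.576 and -0.489), glycolysis genes by 1.334 (1.202 and -0.132) and 4 blood-brain barrier genes by 0.606 (0.388 and -0.218). With the inhibitor, 7 lipid handling genes differed by -0.303 (-0.199 and 0.103). Each of these had an exact p of 0.0286, the smallest possible here, and an adjusted p of 0.0832 over the 32 differences tested, so none passed adjustment. Other lists went opposite ways at a larger p, as 3 NF-kB genes with disease (-0.205 and 0.265, exact p = 0.0571). Medians over all tested members were 0.43 and -0.41. Unnamed clusters, which no comparison between groups used, held 9.28% ± 0.416 of vehicle cells and 5.84% ± 1.36 of WT cells (SD, n = 4 each, exact permutation p = 0.0286).

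The disease-associated microglia genes that rose in the oligodendrocyte sums (Spp1, Lyz2, Trem2 and Apoe) may reflect RNA of microglia carried into those sums. At its measured share, it would give a median of 133.4% of their rise. By gene this was 292.5% for Spp1, 151.7% for Lyz2, 115.1% for Trem2 and 16.7% for Apoe. Trem2 is a marker used for this share, so its value and the medians are partly circular. Vehicle library A11 held 0.997% where A2, A5 and A7 held 0.262% to 0.301%. Without A11 (0.278% ± 0.020, n = 3) the median was 86.9%, with 153.9% for Spp1, 87.1% for Lyz2, 86.8% for Trem2 and 9.0% for Apoe, and without A7 Spp1 stood at 459.1%. For the other 103 genes that rose in oligodendrocytes the median was 0.1%, with 102 of them under 25% (99 without A7) and Fcer1g at 168.9%, and for the 22 rises in astrocytes it was 0.0%, which argues against microglial RNA as the whole cause of either set. Apoe rose in the oligodendrocyte sums by 693 CPM where microglial RNA would give 115 CPM (743.9 and 67.19 CPM without A11), and the rest of that rise stays open. A response of oligodendrocytes themselves to the disease was not tested apart from this.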

How the results depend on the processing

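Leaving out both WT libraries under 500 cells, estimated correlations and fry outside microglia, the relation and the share of microglial RNA without each library, fits within each set of library numbers, and genes named after their values were seen were added after the data were seen, and the other settings were planned. No paired analysis was possible because replicate codes are not shared between groups. Over the 207 gene results the text names, leaving out 1 library at a time kept direction and side of the threshold in 1471 values, ended a call in 107, gained one in 10 and turned the direction in 14. Other settings kept 2190, ended 82, gained 54 and turned 18. At least 1 setting ended the call of 9 of 61 named genes in microglia with disease, 17 of 28 in oligodendrocytes and 13 of 15 in astrocytes, and of 0 of 18 between inhibitor and WT in microglia. Of the list results, leaving out a library kept 236, ended 14, gained 11 and turned 11. Summed microglial counts ran from 771015 to 3164678 UMIs in WT and from 4562442 to 12707085 with vehicle; thinning was run for microglia alone. The looser cell filter left no border macrophage cluster and the stricter one no ependymal cluster to compare, and a minimum of 50 cells removed no microglial library.

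The count of changed genes in microglia fell with every library thinned to 771015 UMIs, to 2011 from 3621 with disease and to 1684 from 3061 between inhibitor and WT, where fewer counts enter the test. With no filter on low genes, counts were 1 in microglia with inhibitor (0 in the reported fit, and 1 with library numbers 1 to 6 alone), 323 (135) and 62 (2) in oligodendrocytes with disease and inhibitor, and 95 (30) and 6 (1) in astrocytes. In oligodendrocytes, a term for library numbers gave 357 genes with disease and 32 with inhibitor, numbers 7 to 12 alone 373 and 6 and numbers 1 to 6 alone 43 with inhibitor, DESeq2 gave 7 and a fit of only the 2 groups 5 with inhibitor, and 60 remained by count with disease without both small WT libraries, where fewer libraries enter. A floor of 10 CPM in at least 4 libraries, stricter than the reported filter in microglia and oligodendrocytes, was looser in astrocytes (9760 genes tested against 6988) and gave 46 there with disease. Also there with disease, a fit of only the 2 groups gave 57, the looser cell filter 113, the stricter 12 and doublets kept 51. With inhibitor DESeq2 and doublets kept gave 0, limma-voom and that floor 2, and a minimum of 50 cells 4. Leaving out 1 library gave 1 (without A2) to 4 (without A7) in oligodendrocytes with inhibitor, 17 (without N9) to 53 (without A5) in astrocytes with disease and 0 (without A5) to 1 with inhibitor. Except for thinning and left-out libraries, the cause was not tested.

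Estimated correlations left 2 of 12 lists in microglia with disease and 0 of 6 with inhibitor, where fry left 1. They left 3 of 7 in oligodendrocytes with disease, and there with inhibitor both left 0 of 4. In astrocytes estimated correlations left 2 of 5 with disease, and both left 0 of 2 with inhibitor. With fry the disease-associated microglia list in astrocytes turned lower with inhibitor (adjusted p = 0.937). In microglia with inhibitor, these lists turned direction when 1 library was left out, with adjusted p from 0.000160 (without A2) to 0.462 (without B12) for interferon-stimulated genes, 0.111 (A11) to 0.948 (A5) for NF-kB genes and 1.15e-05 (A5) to 0.956 (A7) for antigen presentation. The range was 0.0497 (B3) to 0.985 (B4) for lysosome, 0.182 (B12) to 0.879 (B3) for cholesterol synthesis, 0.0404 (B12) to 0.897 (A11) for oxidative phosphorylation and 0.242 (A7) to 0.899 (A11) for blood-brain barrier genes; the cause was not tested.

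Differences in share, in percentage points, that turned sign were of endothelial cells with disease (-0.059, and 0.052 with the looser filter) and, with inhibitor, of microglia (-0.783, and 0.819 with the stricter filter) and, with cells named one by one, of fibroblasts (0.003 to -0.01) and pericytes (0.285 to -0.137). Without 1 library they ran from -0.267 (N8) to 0.054 (N4) for border macrophages, -0.647 (A5) to 0.631 (A2) for endothelial cells and -0.342 (N4) to 0.058 (N10) for neurons with disease. With inhibitor they ran from -0.895 (B4) to 0.6 (B12) for ependymal cells, -0.023 (B8) to 0.032 (A11) for fibroblasts and -2.516 (B12) to 1.47 (B8) for microglia. None of these shares had passed.

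Among genes none of which had passed, Ripk1 in microglia with disease turned from 0.016 to -0.002 with the term for library numbers, -0.012 and -0.046 with the looser and stricter cell filters and -0.097 without both small WT libraries, which gave -0.004 between inhibitor and WT. Thinning turned Tradd to 0.471 in microglia with inhibitor. In astrocytes with inhibitor the looser cell filter gave Bst2 -0.862 and Ifit3 -1.604, and the stricter one Tm4sf1 -0.562. Sod1 there, at 0.005, was -0.010 with no filter and -0.023 with the floor of 10 CPM on low genes, -0.134 with a minimum of 50 cells, -0.036 with the term, and -0.141 and -0.013 with the looser and stricter cell filters. Ripk1 there, at -0.141, was 0.147 with limma-voom, 0.319 with a minimum of 50 cells and 0.293 with the stricter cell filter. Without 1 library Ripk1 ran from -0.081 (N10) to 0.108 (N9) in microglia, -0.281 (A5) to 0.105 (N4) in oligodendrocytes and -0.006 (A2) to 1.052 (A5) in astrocytes with disease, and from -0.699 (A5) to 0.344 (A2) in astrocytes with inhibitor. In microglia with inhibitor Zbp1 ran from -0.704 (A2) to 0.111 (A7), Irf7 from -0.921 (A5) to 0.22 (A7), C3 from -0.334 (A11) to 0.035 (B8) and Ocln from -0.003 (B8) to 0.676 (A11), and Sod1 in astrocytes from -0.174 (A5) to 0.142 (B4). The relation in microglia, -0.0724, was -0.0085 with the disease contrast on A2 and A7 and -0.0076 on A7 and A11, and ran from -0.1159 (A5) to -0.0495 (A7) without 1 library. For these values the cause was not tested.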

Other observations

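The relation between both comparisons in microglia and its divisions of the vehicle libraries were planned, while the lists of glucocorticoid-responsive and clock genes and all other tests in this part were chosen after the results were seen.

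Clock genes, which drive daily rhythms, were lower in microglia of vehicle-treated SOD1 mice than of WT mice. All 6 tested members were lower and 4 fell: Hlf (log2 -2.07, SE 0.34, edgeR adjusted p = 7.32e-05), Per3 (-0.75, SE 0.19, adjusted p = 0.00388), Tef (-0.53, adjusted p = 0.0124) and Nr1d2 (-0.53, adjusted p = 0.0199). Their mean score, in log2(CPM + 1), was 3.27 ± 0.232 against 4.11 ± 0.281 in WT (SD, n = 4 each, exact permutation p = 0.0286, the smallest possible), and 3.14 ± 0.207 (n = 4) with inhibitor. The list had a camera p of 0.00273, and 0.0845 with an estimated correlation. Nr1d2 did not pass without N4 (adjusted p = 0.111), A7 (0.0572) or both N8 and N10 (0.0530), nor Tef without both (0.112), and with every library thinned neither Per3 (0.0951) nor Tef (0.197) did. In astrocytes 7 of 8 members were lower with disease, none passing, with a score difference of -0.511 (exact permutation p = 0.1, n = 3 each, the smallest possible). In oligodendrocytes the score differed by 0.133 (exact permutation p = 0.429, n = 4 each).

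Glucocorticoid-responsive genes were higher in oligodendrocytes of vehicle-treated SOD1 mice than of WT mice, 18 of 19 tested members being higher and 13 passing (median log2 1.24). The list was written after these genes had been seen in the same cells, so this describes them and tests nothing. Fkbp5, a chaperone of steroid receptors, rose from 5.41 ± 4.71 to 42.8 ± 13.3 CPM (SD, n = 4 each; log2 2.60, SE 0.40, edgeR adjusted p = 0.00381, and log2 3.41 without N4). Errfi1 (1.24, SE 0.17, adjusted p = 0.000341), Arrdc2 (1.41, SE 0.17, adjusted p = 0.000108), Klf9 (0.76, SE 0.15, adjusted p = 0.00683) and the metallothionein gene Mt1 (1.11, SE 0.17, adjusted p = 0.000687) also rose, Klf9 not without both N8 and N10 (0.203). The score was 6.63 ± 0.184 with vehicle and 5.28 ± 0.435 in WT (SD, n = 4 each). With the inhibitor 17 of 19 members were lower than with vehicle and none passed (3 with a term for library numbers), at a score of 6.18 ± 0.116 (SD, n = 4; median log2 -0.51). Genes seen to rise in the vehicle libraries are expected to be lower in a second comparison against those libraries, so this too describes the list and tests nothing. Errfi1 (-0.76), Arrdc2 (-0.83) and Klf9 (-0.63) did not pass there with edgeR (adjusted p = 0.242, 0.169 and 0.242) but did with DESeq2 (0.0421, 0.00952 and 0.0421), and Arrdc2 did with edgeR without B12 (0.0422). Mt1 stood at 0.04 (SE 0.16, adjusted p = 1.00) between inhibitor and vehicle and 1.15 (SE 0.17) between inhibitor and WT. In astrocytes 14 of 16 members were higher with disease, 4 of them passing, and 12 of 16 were lower with inhibitor, none passing, with score differences of 0.721 (exact permutation p = 0.1, n = 3 each) and -0.417 (exact permutation p = 0.0571, n = 4 and 3).

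For the lower score of glucocorticoid-responsive genes with the inhibitor in oligodendrocytes, a general response to stress or dissociation is a candidate explanation, since immediate early genes outside the list were lower too (8 of 9 members, score difference -0.334, exact permutation p = 0.114, n = 4 each). In astrocytes, where the score difference of -0.417 had an exact permutation p of 0.0571, immediate early genes differed by 0.072 (exact permutation p = 0.714, n = 4 and 3). Tissue taken at another time of day cannot be told apart from a difference between groups by the clock genes, whose score differed by -0.032 (exact permutation p = 0.971), because a p that misses the threshold does not show equal levels. Nor can chance be excluded by the exact p of 0.0286 for a list written after its genes were seen. The vehicle libraries shared by both comparisons stay open as well, since simulated unchanged groups gave opposite signs for 31.03 of the 32 genes with the smallest p with inhibitor, and the real ones for 31. A biological effect of RIPK1 inhibition on this response stays open as a hypothesis, as do handling and dosing of the mice, which were not tested.

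The negative covariance of the inhibitor and disease effects in microglia, -0.0724, could arise from the vehicle libraries that both comparisons share. Simulated unchanged groups gave -0.0210, a difference of -0.0514, and with the vehicle libraries divided all 6 values, from the same 4 libraries, lay below 0, with -0.0085 and -0.0076 near it. Shared libraries as the whole cause stay open, because the simulated SD of 0.0009 leaves out shifts of whole libraries, and assignments that share vehicle places in the same way reached -0.131. Chance in which SOD1 libraries carried which treatment cannot be excluded, since 11 of the 70 assignments gave a covariance as negative (the most negative other -0.131). In oligodendrocytes the covariance differed from the simulated one by -0.0081, and 5 of 6 divisions of the vehicle libraries were negative, from -0.0204 to 0.0331. A partial shift of microglia toward WT under the inhibitor therefore remains a hypothesis.

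Other splits of the same libraries into groups of the same sizes were run for each count. For 3621 genes in microglia with disease and 3061 between inhibitor and WT, 1 of 35 splits gave as many (highest others 0 and 1). Splits cannot judge chance there, since each other split mixes WT with SOD1, adding the disease effect to the spread. Nor can they for 0 genes there between inhibitor and vehicle, since all 35 give at least 0 (highest other 453). Chance cannot be excluded for 2 genes in oligodendrocytes with inhibitor (3 of 35, highest other 470) or for 135 genes there with disease (2 of 35, highest other 1868, no further split reaching 135). The counts of 453, 470 and 1868 came from the split of library numbers 1 to 6 against 7 to 12 and lay far above the real counts of 0, 2 and 135, which points to a structure of the libraries by number. With a term for these numbers, microglia had 4521 genes with disease and 0 with inhibitor, and oligodendrocytes 357 and 32. With that term, among the 18 splits keeping 2 libraries of each number set in each group, the highest other gave 0 in microglia with disease, and 15 and 3 in oligodendrocytes with disease and inhibitor. These 18 are too few for a share under 0.05. In astrocytes chance cannot be excluded for 1 gene with inhibitor (7 of 35, highest other 74). The 10 splits are too few for the disease comparison in astrocytes, with 30 genes (highest other 2) and 5 lists (highest other 6). For counts of lists chance cannot be excluded in microglia with disease (12 lists, 6 of 35, highest other 14) or inhibitor (6 lists, 18 of 35, highest other 9). Nor can it in oligodendrocytes with disease (7 lists, 5 of 35, highest other 7) or inhibitor (4 lists, 13 of 35, highest other 8), or in astrocytes with inhibitor (2 lists, 15 of 35, highest other 7).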
